A study of Mus musculus with 8 samples.

How the data were processed

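Kidney total RNA of 8 NZBWF1 mice was measured on 1-colour Affymetrix Clariom S Mouse arrays, 4 mice at 8 weeks and 4 at 28 weeks of age. Per the labels' protocols, RNA was extracted with Trizol and labelled as biotinylated cRNA. The values used are log2 expression values deposited by the authors, and the submitters' processing notes name RMA, which corrects the background, quantile-normalizes the arrays and summarises the probes of a transcript. The RMA version, software and settings are not given in the sources used here. The log base is not stated either and was taken as 2 from the convention of RMA and the range of the values, 2.31 to 19.89, so the folds given here rest on that. RMA compresses folds, most of all for dim probes, and gives no detection call, so a low value is not proof of absence. The deposited columns were not of one distribution, with array medians from 5.98 to 6.14 and lower quartiles from 4.16 to 4.44. No column outside the 8 samples was used.

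All 22206 probes were tested without a filter. The platform annotation gave 1 gene symbol to 19572 probes (88.1%), several to 0 and none to 2634, which are counted but not named. Symbols were compared with a RefSeq gene table through the gene identifier, and none needed updating. The named probes covered 19505 genes, 55 of them with several probes, and for those the brightest probe stood for the gene. No scan date or batch was in the sources used here, so batches could not be examined. No pair of arrays were duplicates.

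Groups were taken from the sample labels. Replicate numbers are not shared between the ages, so no pairing was used, and each array was treated as 1 mouse, as the series' design gives 4 mice per age. The log2 difference, 28 weeks minus 8 weeks, was tested per probe with lmFit and eBayes in limma (version 3.58.1, R version 4.3.3), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. A difference of at least 2-fold is a log2 difference of at least 1. The variance prior had 4.13 degrees of freedom.

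The gene lists, 55 with 1219 entries and 1132 different names, were written before the data were examined, as were the tests, the rule for naming genes and most alternatives. Of the 1132 names 1007 were on a named probe, and the rest were not analysed here. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with fry, and with camera on ranks. The per-mouse list score is the mean over members of the value minus the 8-week mean of the gene, compared by an exact two-sided permutation test over 70 arrangements. Spread was compared as the median over probes of the log2 ratio of SDs, with an exact test over 35 splits.

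The naming rule took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, without predicted, clone or receptor-family names. For each list it took up to 4 members past the threshold in the commoner direction and 1 in the opposite one, or the 2 members with the smallest p where none passed. It always named a further 24 genes, of which 18 were on a named probe.

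Alternatives were other normalizations (array medians, quantiles, ribosomal and reference genes), filters on dim probes (leaving out the dimmest 33.3% or 50% of probes), 1 named probe per gene, eBayes with trend and robust options, array weights, an unmoderated test with unequal variances, 1 surrogate variable, stricter thresholds (adjusted p under 0.01, and treat against a log2 difference of 0.5), and each array left out in turn. Cyclic loess and leaving out both 8-week replicate 1 and 28-week replicate 7 were added after seeing the data.

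The code was tested on simulated data. In 5 simulated sets of 22206 genes in 4 against 4 arrays, with 200 genes changed per set, limma recovered 1.6% of genes changed by 0.5 on the log2 scale, 60% of those changed by 1, 97.2% of those changed by 2 and 99.6% of those changed by 3, with a mean of 6.8 unchanged genes called per set. Camera at the preset correlation called 0 of 54 unchanged lists when genes varied independently. When the members of each list shared an array effect with an SD of 0.3 and no group effect, it called 22 of 54, and 0 with an estimated correlation. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.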

Results

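Gene expression was measured in the kidneys of NZBWF1 mice, the hybrid of the New Zealand Black and New Zealand White strains, which develops a lupus-like autoimmune disease with nephritis as it ages. Total RNA from 4 mice at 8 weeks of age and from 4 mice at 28 weeks was hybridized to 1-colour Clariom S Mouse arrays, 1 array per mouse. The labels number the 8-week mice as replicates 1 to 4 and the 28-week mice as replicates 6 to 9. Values are log2 intensities after robust multi-array averaging (RMA) for 22206 probes. Array medians lay between 5.98 and 6.14. The comparison asks how the kidney mRNA profile differs between the 2 ages. Values below are mean log2 RMA value ± SD, with n = 4 arrays at each age, and adjusted p is from limma with Benjamini-Hochberg adjustment over all probes. The number of arrays limits the precision of every value.

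The arrays of one age did not all group together. The first principal component held 39.4% of the variance and the second 25.1%. On the first component the 8-week arrays scored between -39.5 and -7.66, and 28-week replicates 6, 8 and 9 between 31.8 and 59.9. Replicate 7 of the 28-week group scored -12.9, inside the range of the 8-week arrays. Its mean correlation across probes was 0.9897 with the 8-week arrays and 0.9858 with the other 28-week arrays. On the second component 8-week replicate 1 scored 65.1, while the other 7 arrays lay between -27.8 and 15.3. Probes for the Y-linked genes Eif2s3y, Kdm5d and Uty lay close to the lowest deposited value of 2.31 in both groups. Eif2s3y was 2.73 ± 0.18 at 8 weeks and 2.72 ± 0.12 at 28 weeks, Kdm5d was 3.20 ± 0.40 at 8 weeks and 2.90 ± 0.28 at 28 weeks, and Uty was 3.07 ± 0.34 at 8 weeks and 3.22 ± 0.32 at 28 weeks.

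**Figure D1:**
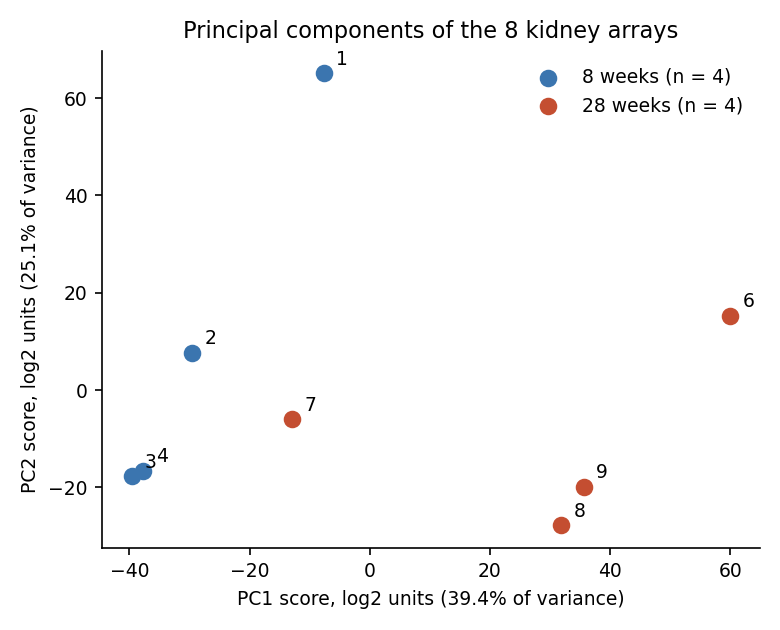
Scores of the 8 arrays on the first (x axis, 39.4% of variance) and second (y axis, 25.1% of variance) principal components of the log2 values, with 1 point per mouse labelled by replicate number and coloured by age. Replicate 7 of the 28-week group lies at -12.9 on the first component, among the 8-week arrays, and 8-week replicate 1 lies alone at 65.1 on the second.

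At 28 weeks the largest rise among the named genes past the threshold was that of Igf2, a fetal growth factor, which was 8.82 ± 0.37 at 8 weeks and 13.08 ± 0.54 at 28 weeks (19.1-fold higher, adjusted p = 0.000537). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 11.9-fold (adjusted p = 0.00146), and the adhesion molecule Vcam1 rose 6.14-fold (adjusted p = 0.0423). The largest fall among the genes that the naming rule allows was that of Dbp, a clock-controlled transcription factor, which was 16.46 ± 0.14 at 8 weeks and 11.85 ± 1.69 at 28 weeks (24.6-fold lower, adjusted p = 0.0214). The predicted gene Gm6300, which the rule leaves out and which was chosen after its values were seen, fell 40.1-fold (adjusted p = 0.00782). Dbp was followed by Nat8f6 and Nat8f3, members of a cluster of N-acetyltransferase genes of the proximal tubule, which were 11.2-fold and 11-fold lower. Serpina6, the gene of corticosteroid-binding globulin, fell 8.35-fold (adjusted p = 0.005).

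In total 215 of 22206 probes changed at an adjusted p under 0.05, 99 of them higher and 116 lower at 28 weeks, and 164 of the 215 differed at least 2-fold. In all 215 the 4 arrays of one age lay above the 4 of the other. Such separation was seen in 1934 probes (8.71%), where chance gives 2.86%. With each array centred on ribosomal protein and reference genes, which moved the median difference of all probes to -0.14 from -0.01, 88 probes were higher and 212 lower. The number of calls depended on single arrays. It was 94, 36, 30 and 26 without 8-week replicates 1, 2, 3 and 4, and 56, 1237, 28 and 25 without 28-week replicates 6, 7, 8 and 9. Without both 8-week replicate 1 and 28-week replicate 7, a choice made after seeing the data, it was 1384.

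The other genes among the 12 largest rises past the threshold were Arntl, Dcdc2a, H2-Ab1, Npas2, Cyth4, Csf1, Scin, Anxa2 and Cyp4a12a, with folds from 3.93 for the fatty acid hydroxylase gene Cyp4a12a to 7.41 for the clock gene Arntl. Csf1, the growth factor of macrophages, was 7.92 ± 0.31 at 8 weeks and 10.05 ± 0.81 at 28 weeks (adjusted p = 0.0309). Scin, which encodes the actin-severing protein scinderin, rose 4.16-fold, and Cyth4 rose 4.38-fold. Among the 12 largest falls past the threshold, Nat8f7, Nat8f5 and Nat8f1 were 8.31-fold, 6.04-fold and 5.73-fold lower. These Nat8 family genes are close paralogs whose probes may share signal, so their separate folds are uncertain. Clec2h fell 7.85-fold, Ly6f 6.66-fold, the calcium-binding protein gene S100g 5.48-fold, and the clock genes Ciart and Per3 8.22-fold and 5.43-fold. Of the 46 genes named by the naming rule that passed the threshold, all 46 kept their sign in each of the 8 fits that left out 1 array. That was fixed in advance, because the groups did not overlap in any of these genes. The 13 that also passed in all 8 were Igf2, Cdkn1a, Pfkp, Nat8f1, Nat8f3, Nat8f5, Nat8f6, Serpina6, Ciart, Clec2h, Ly6f, Lpl and Slc22a30. The calls of the other 33 ended without at least 1 array, at adjusted p of up to 0.178, and 19 of them passed in none of the 8 fits but the one without 28-week replicate 7.

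**Figure D2:**
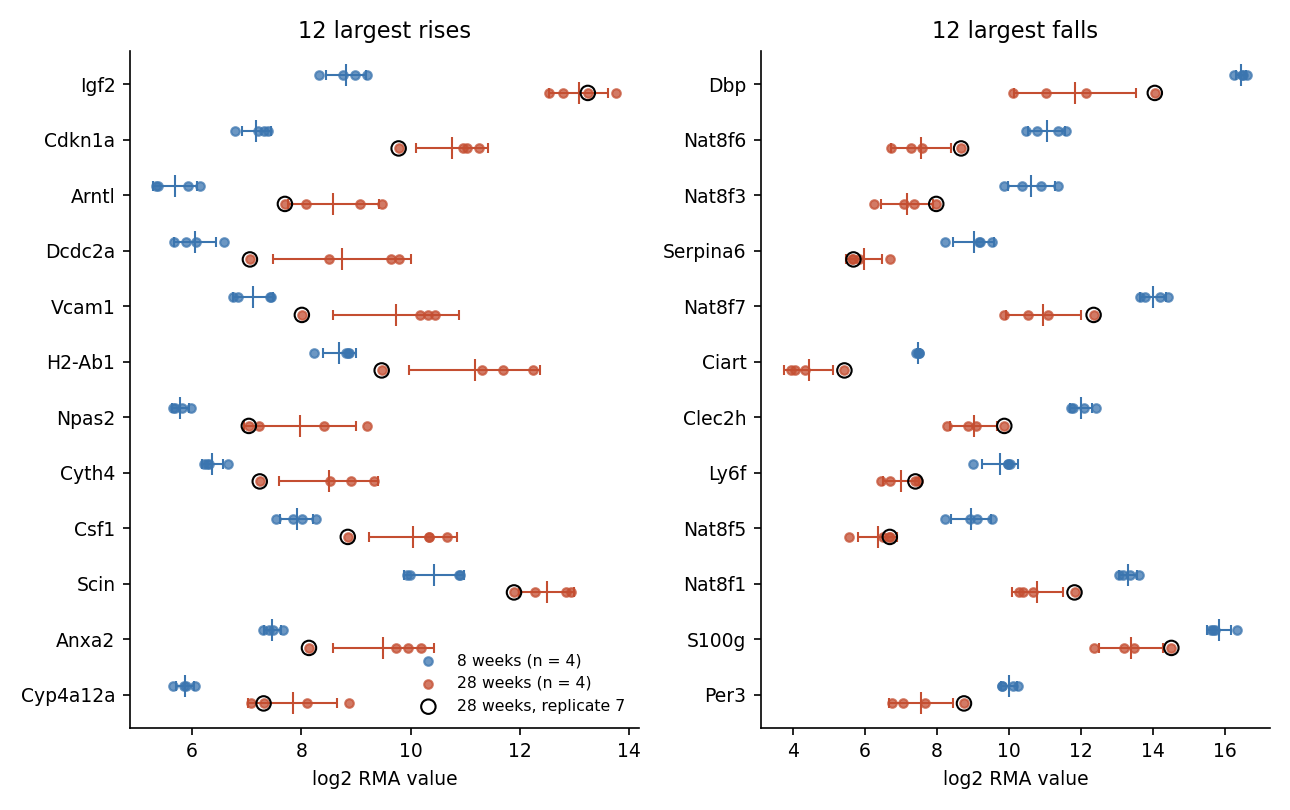
Log2 RMA values (x axes) of the 12 named genes with the largest rise and the 12 with the largest fall among those past the threshold, with 1 point per mouse, ticks for group means, bars for SD (n = 4 per age), and a ring around 28-week replicate 7. The groups do not overlap in any of these genes, and for Igf2 replicate 7 lies at 13.24, within the range of the other 28-week mice.

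Most lists of immune genes were higher on average at 28 weeks. Of 25 macrophage and monocyte markers, 24 had a positive difference and none passed the threshold over all probes, while 23 passed when adjusted over the list alone. Their mean was 3.96-fold higher (camera adjusted p = 9.66e-17, and adjusted p = 0.252 with an estimated correlation). Lyz2, a lysozyme gene of myeloid cells, was 7.5 ± 0.94 at 8 weeks and 12.04 ± 2.29 at 28 weeks (adjusted p = 0.0607), and the Fc receptor gene Fcgr3 was 8.89 ± 0.21 at 8 weeks and 10.05 ± 0.47 at 28 weeks (adjusted p = 0.0506). The pan-leukocyte gene Ptprc was 7.25 ± 0.18 at 8 weeks and 8.95 ± 1.55 at 28 weeks (adjusted p = 0.215) and the macrophage gene Adgre1 was 5.96 ± 0.32 at 8 weeks and 7.62 ± 1.48 at 28 weeks (adjusted p = 0.208). The list score, the mean log2 difference of the members from the 8-week mean, was 2.94, 2.49 and 2.36 in 28-week replicates 6, 8 and 9 and 0.147 in replicate 7, where the 8-week mice spanned -0.161 to 0.193. Genes of Fc receptors and their proximal signalling were 2.68-fold higher on average, with none of 15 past the threshold and 12 adjusted over the list alone (camera adjusted p = 1.18e-08, and adjusted p = 0.27 with an estimated correlation). The Fc receptor list score was -0.0242 in 28-week replicate 7 and 2.43, 1.78 and 1.5 in replicates 6, 8 and 9. Fcer1g, the common signalling chain of Fc receptors, was 6.35 ± 0.12 at 8 weeks and 10.34 ± 2.39 at 28 weeks (adjusted p = 0.0777).

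The antigen presentation and interferon lists were also higher on average. Of 11 MHC class II genes 1, H2-Ab1, passed over all probes (8.70 ± 0.30 at 8 weeks and 11.17 ± 1.2 at 28 weeks, adjusted p = 0.0495), and 7 were higher and 1 lower adjusted over the list alone. The list was 2.95-fold higher on average (camera adjusted p = 6.08e-07, and adjusted p = 0.27 with an estimated correlation). The MHC class I list was 1.68-fold higher on average, without a member past the threshold over all probes and with 9 of 14 adjusted over the list alone. H2-K1 was 12.05 ± 0.39 at 8 weeks and 13.52 ± 0.81 at 28 weeks and the peptide transporter gene Tap2 was 6.45 ± 0.15 at 8 weeks and 7.08 ± 0.26 at 28 weeks. Among 42 type I interferon-stimulated genes 40 had a positive difference, 2 passed over all probes and 25 adjusted over the list alone. Those 2 were Ddx58, which encodes the RNA sensor RIG-I (2.15-fold, adjusted p = 0.0474), and Isg15, which encodes a ubiquitin-like modifier (1.97-fold, adjusted p = 0.0464). Ifit1 was 5.59 ± 0.32 at 8 weeks and 6.74 ± 0.92 at 28 weeks (adjusted p = 0.188). None of 19 interferon-gamma-induced genes passed over all probes and 10 did adjusted over the list alone. The chemokine gene Cxcl10 had an adjusted p of 0.0501 and the GTPase gene Igtp one of 0.0752, with log2 differences of 1.79 and 1.76. Camera adjusted p was 6.29e-07 for MHC class I, 2.16e-16 for type I interferon and 1.64e-07 for interferon-gamma genes. For each of these lists adjusted p = 0.27 with an estimated correlation. In 28-week replicate 7 the scores of the MHC class II, MHC class I, type I interferon and interferon-gamma lists were 0.247, 0.0654, 0.0171 and 0.0401.

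Inflammatory signalling genes also had higher means. In the TNF and NF-kappa-B response list Vcam1 was the only one of 23 members past the threshold over all probes (7.12 ± 0.37 at 8 weeks and 9.74 ± 1.16 at 28 weeks), and 11 passed adjusted over the list alone. Of 22 complement genes none passed over all probes, with 12 higher and 1 lower adjusted over the list alone. The log2 difference was 1.03 for C5ar1, a receptor of the complement fragment C5a, and 1.72 for C7. The C5ar1 probe was dim, with a mean of 4.07 at 8 weeks. Of 22 leukocyte-attracting chemokines none passed over all probes and 12 did adjusted over the list alone, with log2 differences of 1.79 for Cxcl10 (adjusted p = 0.0501) and 1.22 for Cxcl16 (adjusted p = 0.0516). Tlr3 and Myd88 had the smallest p of 19 nucleic-acid sensing and inflammasome genes, of which 7 passed adjusted over the list alone, with log2 differences of 0.99 and 0.88. In the list of lymphoid tissue organising genes Bcl6, a transcriptional repressor of germinal centre B cells, rose 3.14-fold (adjusted p = 0.0167) and 2 of 17 passed adjusted over the list alone. Bcl6 was highest in 28-week replicate 7 (7.99, against 7.67 to 7.82 in the other 28-week mice). In that mouse the B cell list score was 0.0912, the lowest at 28 weeks, so Bcl6 did not follow the B cell markers there. Another member, the B-cell attractant gene Cxcl13, had a log2 difference of 3.26 (adjusted p = 0.174). Camera adjusted p was 9.68e-09 for the TNF and NF-kappa-B list, 3.07e-06 for complement, 1.85e-06 for chemokines, 8.19e-07 for nucleic-acid sensing and 0.00123 for lymphoid organisation. With an estimated correlation adjusted p = 0.252 for the TNF and NF-kappa-B, complement and lymphoid lists, and adjusted p = 0.27 for the chemokine and nucleic-acid sensing lists. In 28-week replicate 7 the scores were 0.143 for the TNF and NF-kappa-B, 0.0889 for the complement, -0.0525 for the chemokine, -0.145 for the nucleic-acid sensing and 0.221 for the lymphoid list, and the lowest scores in the other 28-week mice were 0.841, 1.22, 0.964, 1.06 and 0.357.

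None of the lymphocyte, dendritic cell and granulocyte markers passed the threshold over all probes. The T cell list was 1.26-fold, the B cell list 1.35-fold and the dendritic cell list 1.25-fold higher on average, with camera adjusted p of 0.000135, 0.000941 and 0.0127, and for each adjusted p = 0.27 with an estimated correlation. None of 24 T cell or 17 B cell markers and 2 of 16 dendritic cell markers passed adjusted over the list alone. Cd3e was 4.29 ± 0.43 at 8 weeks and 5.37 ± 0.53 at 28 weeks, and the log2 difference was 0.73 for the T cell gene Icos, 0.93 and 1.25 for the B cell genes H2-Ob and Bank1, and 1.13 and 1.19 for the dendritic cell genes Bst2 and Xcr1. The scores of the T cell, B cell and dendritic cell lists in 28-week replicate 7 were 0.0361, 0.0912 and 0.0802, and in the other 28-week mice at least 0.299, 0.224 and 0.351. The dendritic cell call ended without 8-week replicate 2 (adjusted p = 0.0845). The NK and cytotoxic, plasma cell, neutrophil, and mast cell lists were not called, at camera adjusted p of 0.11, 0.394, 0.11 and 0.518, with mean log2 differences of 0.17, 0.51, 0.53 and -0.12. The neutrophil list was called without 8-week replicate 3 (adjusted p = 0.033). Adjusted over the list alone 1 of 13 plasma cell and 3 of 16 neutrophil markers were higher, and none of 15 NK and 10 mast cell markers passed. Single members of these lists had large differences with a large spread. The immunoglobulin joining chain gene Jchain was 4.38 ± 0.66 at 8 weeks and 9.15 ± 3.09 at 28 weeks (adjusted p = 0.0971). Lcn2, a neutrophil and injured-tubule gene, was 7.15 ± 0.83 at 8 weeks and 13.41 ± 3.59 at 28 weeks (adjusted p = 0.0752), with 8.21 in 28-week replicate 7. Differences in the same lists were 0.52 for Sdc1, 1.30 for Csf3r, 0.85 for Ccl5, 0.73 for Gzmk, -0.33 for Kit and -0.17 for Mcpt4. The probes of Csf3r, Ccl5, Gzmk and Mcpt4 were dim, with 8-week means of 3.775, 3.99, 3.52 and 3.81.

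**Figure D3:**
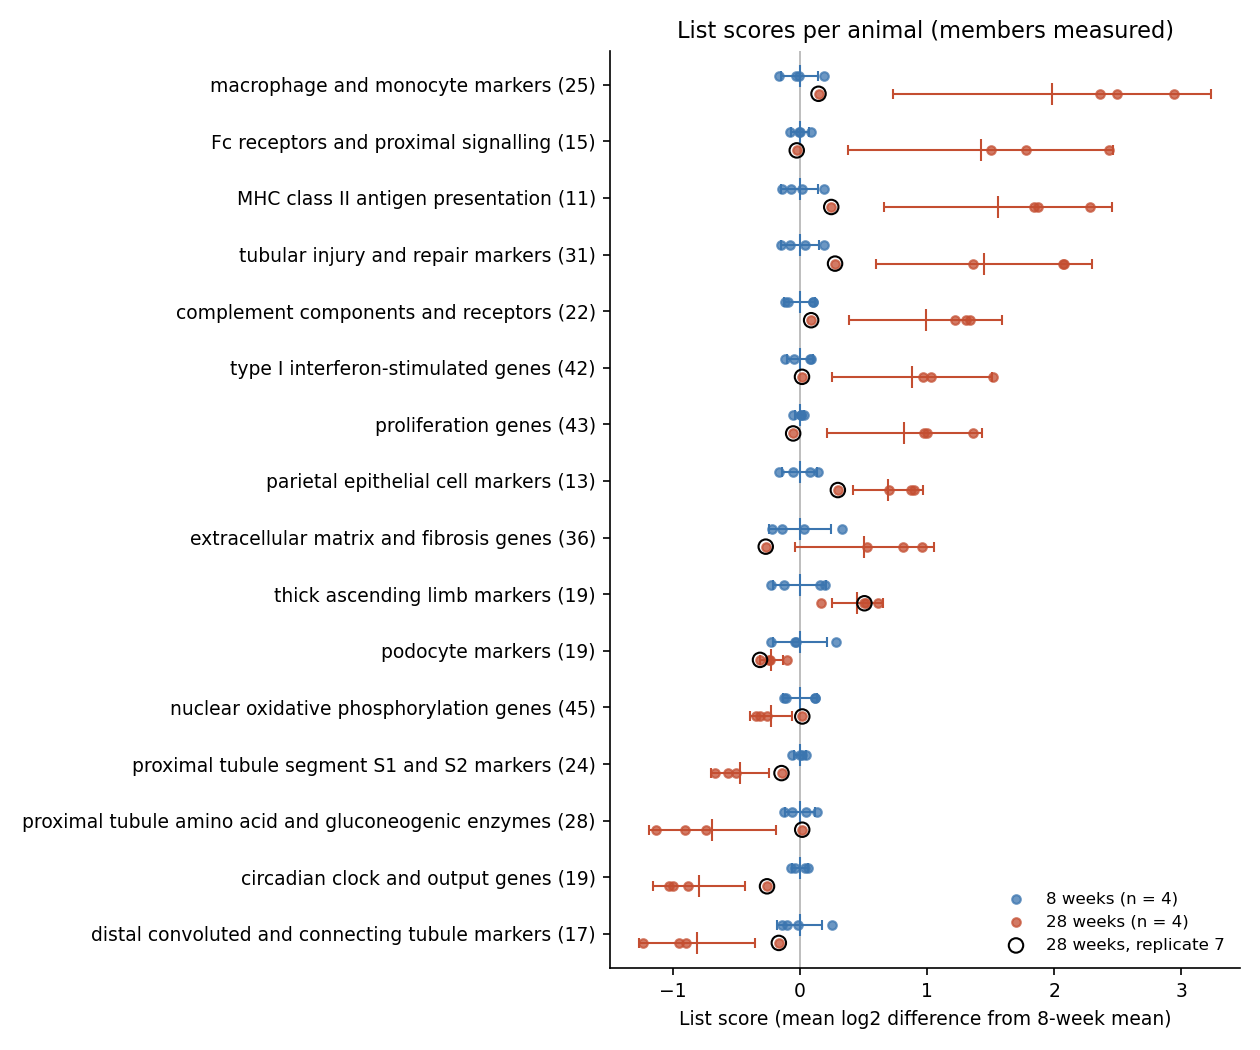
List score per mouse (x axis, mean log2 difference of the list's members from the 8-week mean) for 16 of the gene lists, with the number of measured members in brackets, 1 point per mouse, ticks for group means, bars for SD (n = 4 per age), and a ring around 28-week replicate 7. For macrophage markers 28-week replicates 6, 8 and 9 lie between 2.36 and 2.94 and replicate 7 lies at 0.147.

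Tubular injury and repair markers were higher on average at 28 weeks. Of 31 measured markers 29 had a positive difference, 4 passed over all probes, and 19 were higher and 1 lower adjusted over the list alone. Those past the threshold were Cdkn1a (7.18 ± 0.27 at 8 weeks and 10.76 ± 0.66 at 28 weeks), Dcdc2a (6.49-fold), Vcam1 and the annexin gene Anxa2 (4.1-fold). The list mean was 2.73-fold higher (camera adjusted p = 3.58e-15, and adjusted p = 0.252 with an estimated correlation). Havcr1, which encodes the injury marker KIM-1, was 14.94 ± 0.65 at 8 weeks and 15.74 ± 1.56 at 28 weeks (adjusted p = 0.655). Proliferation genes were 1.77-fold higher on average, with 40 of 43 differences positive, none past the threshold over all probes, and 25 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.03e-14, and adjusted p = 0.27 with an estimated correlation). The mitotic checkpoint gene Bub1b and the ubiquitin-conjugating enzyme gene Ube2c had log2 differences of 0.93 and 2.0, at adjusted p of 0.0501 and 0.0576. The Bub1b probe was dim, with means of 3.25 at 8 weeks and 4.175 at 28 weeks. Extracellular matrix and fibrosis genes were 1.42-fold higher, with none of 36 past the threshold over all probes and 4 adjusted over the list alone (camera adjusted p = 0.000149, and adjusted p = 0.426 with an estimated correlation). Tgfb1 was 8.51 ± 0.21 at 8 weeks and 9.84 ± 0.61 at 28 weeks, the tenascin gene Tnc had a log2 difference of 1.90, and the fibrillar collagen gene Col1a1 one of 0.26 (adjusted p = 0.704). Scores of the tubular injury, proliferation and matrix lists in 28-week replicate 7 were 0.277, -0.0524 and -0.268, against lowest scores of 1.36, 0.977 and 0.529 in the other 28-week mice.

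Lists of proximal tubule segment S1 and S2 markers and of metabolic enzymes were lower on average at 28 weeks. Of 24 markers of proximal tubule segments S1 and S2, 23 had a negative difference. One of them, Slc22a6, a basolateral organic anion transporter gene, passed over all probes (15.51 ± 0.21 at 8 weeks and 14.60 ± 0.15 at 28 weeks, adjusted p = 0.0313), and 10 passed adjusted over the list alone. The list was 1.38-fold lower on average (camera adjusted p = 3.29e-09, and adjusted p = 0.252 with an estimated correlation). The list score was -0.144 in 28-week replicate 7 and -0.505 or lower in the other 28-week mice. Slc34a1, the main phosphate transporter gene, was 18.21 ± 0.24 at 8 weeks and 17.64 ± 0.23 at 28 weeks (adjusted p = 0.145), and the endocytic receptor gene Lrp2 was 18.13 ± 0.12 at 8 weeks and 18.05 ± 0.23 at 28 weeks (adjusted p = 0.877). The segment S3 list was not called (camera adjusted p = 0.0645), but its member Slc22a30 was 13.50 ± 0.11 at 8 weeks and 11.70 ± 0.15 at 28 weeks (adjusted p = 0.000795), and 3 of 17 members passed adjusted over the list alone. The S3 list was called without 8-week replicate 3 (adjusted p = 0.033), 28-week replicate 6 (0.0337) or 28-week replicate 7 (0.03). Proximal tubule enzymes of amino acid metabolism and gluconeogenesis were 1.61-fold lower, with 26 of 28 differences negative and 13 past the threshold adjusted over the list alone (camera adjusted p = 1.24e-10, and adjusted p = 0.27 with an estimated correlation). Over all probes Agxt2, an aminotransferase gene, and Ttc36 passed, at 2.45-fold and 2.37-fold lower. The list score was 0.0188 in 28-week replicate 7 and -0.737 or lower in the other 28-week mice.

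The fatty acid oxidation and oxidative phosphorylation lists were also lower on average. Fatty acid oxidation and peroxisomal genes had 28 of 34 differences negative and a mean 1.17-fold lower (camera adjusted p = 6.31e-06, and adjusted p = 0.252 with an estimated correlation). Over all probes the fatty acid hydroxylase gene Cyp4a14 fell 2.11-fold and Cyp4a12a rose 3.93-fold, and adjusted over the list alone 13 members were lower and 1 higher. Of 45 nuclear oxidative phosphorylation genes 40 had a negative difference and none passed, over all probes or over the list alone (camera adjusted p = 2.43e-05, and adjusted p = 0.418 with an estimated correlation). In 28-week replicate 7 the oxidative phosphorylation score was 0.0194, inside the range of the 8-week mice, and in the other 28-week mice it was -0.256 or lower. The respiratory chain genes Ndufa1 and Cox7a2 had log2 differences of -0.90 and -0.68. The glycolysis and hypoxia list was called upwards (camera adjusted p = 0.0272, and adjusted p = 0.27 with an estimated correlation), with the phosphofructokinase gene Pfkp 2.63-fold higher (adjusted p = 0.00782) and the mitophagy receptor gene Bnip3 1.96-fold lower. Adjusted over the list alone 5 of its 20 members were higher and 2 lower. That call ended without 8-week replicate 3 (adjusted p = 0.0921), 28-week replicate 6 (0.0554) or 28-week replicate 7 (0.091).

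Other nephron segments differed in direction. Distal convoluted and connecting tubule markers were 1.75-fold lower on average, and 2 of 17, the calcium-binding protein genes S100g (15.85 ± 0.33 at 8 weeks and 13.39 ± 0.89 at 28 weeks) and Pvalb (11.87 ± 0.43 at 8 weeks and 9.44 ± 1.09 at 28 weeks), passed over all probes. Adjusted over the list alone 9 were lower and 1 higher (camera adjusted p = 3.92e-06, and adjusted p = 0.27 with an estimated correlation). The list score was -1.23, -0.895 and -0.949 in 28-week replicates 6, 8 and 9, -0.165 in replicate 7, and -0.141 or higher in the 8-week mice. Egf and Kl are not in the distal list. Egf, a member of the thick ascending limb list, was 15.73 ± 0.05 at 8 weeks and 14.88 ± 0.46 at 28 weeks (adjusted p = 0.095). Its mean was thus lower, while that of its list was higher. Kl, the gene of the phosphate-regulating protein klotho, was 16.09 ± 0.21 at 8 weeks and 14.85 ± 0.67 at 28 weeks (adjusted p = 0.081). Thick ascending limb and thin limb lists were 1.37-fold and 1.56-fold higher (camera adjusted p = 2.72e-05 and 0.000516, and adjusted p = 0.252 and 0.27 with an estimated correlation). Adjusted over the list alone 8 of 19 thick limb markers were higher and 1 lower, and 4 of 11 thin limb markers were higher. The prostaglandin synthase gene Ptgs2 rose 2.1-fold and Bst1 rose 3.1-fold, while Umod, the uromodulin gene, was 18.37 ± 0.10 at 8 weeks and 18.60 ± 0.12 at 28 weeks (adjusted p = 0.494). Intercalated cell markers were called downwards (mean log2 difference -0.05, median -0.372, camera adjusted p = 0.00386, and adjusted p = 0.27 with an estimated correlation), with Atp6v1c2, a proton pump subunit gene, at a log2 difference of -0.85 and 6 members lower and 1 higher of 19 adjusted over the list alone. That list also holds Jchain, with a log2 difference of 4.77, and the exact permutation p of its score was 0.686. Principal cell markers were not called (camera adjusted p = 0.535), with 1 of 17 higher and 1 lower adjusted over the list alone. Their member Sgk1, an aldosterone-induced kinase gene, rose 2.41-fold (adjusted p = 0.0495).

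Among lists of glomerular cell types, parietal epithelial cell markers were 1.62-fold higher (camera adjusted p = 1.06e-06, and adjusted p = 0.252 with an estimated correlation). The arrays measured kidney RNA, so this difference cannot be placed in the glomerulus. The member Cdh6 is also in the tubular injury list. Of 13 markers Scin and the tight junction gene Cldn1 (2.35-fold, adjusted p = 0.0456) passed over all probes and 8 adjusted over the list alone. Podocyte markers had 15 of 19 differences negative and none past the threshold over all probes or the list alone (camera adjusted p = 0.00404, and adjusted p = 0.275 with an estimated correlation). The podocyte call ended without 8-week replicate 1 (adjusted p = 0.0601). Nphs1, the nephrin gene of the slit diaphragm, was 8.71 ± 0.46 at 8 weeks and 8.76 ± 0.09 at 28 weeks (adjusted p = 0.957), and the log2 differences of Cd2ap and Vegfa were 0.72 and -0.68. Endothelial and mesangial lists were not called (camera adjusted p = 0.733 and 0.0605). The endothelial list's member Igfbp3 fell 2.79-fold (adjusted p = 0.0367), the 1 of 26 that passed adjusted over the list alone, and the pericyte genes Rgs5 and Mcam had log2 differences of 0.76 and 1.01. None of 16 mesangial markers passed adjusted over the list alone. The mesangial list was called upwards without 8-week replicate 1 (adjusted p = 0.00785) and without 28-week replicate 7 (0.0135), 8 (0.0403) or 9 (0.0426).

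Circadian clock and output genes moved in both directions. Of 19 members 5 fell and 2 rose over all probes, and 12 fell and 4 rose adjusted over the list alone. The falling genes included the clock-controlled genes Dbp, Ciart and Per3 and the nuclear receptor gene Nr1d2 (2.96-fold lower, adjusted p = 0.0457). The fifth was Tef, a relative of Dbp outside the naming rule and chosen after its values were seen (2.42-fold lower, adjusted p = 0.0426). The clock activator genes Arntl and Npas2 rose. Arntl was 5.70 ± 0.40 at 8 weeks and 8.59 ± 0.83 at 28 weeks (adjusted p = 0.0132), and Npas2 rose 4.54-fold (adjusted p = 0.044). The list as a whole was called downwards (camera adjusted p = 7.1e-05, and adjusted p = 0.252 with an estimated correlation). The labels give no time of day at which the kidneys were collected. In 28-week replicate 7 Dbp was 14.06 and Arntl 7.70, and the list score was -0.258, against -0.877 or lower in the other 28-week mice.

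**Figure D4:**
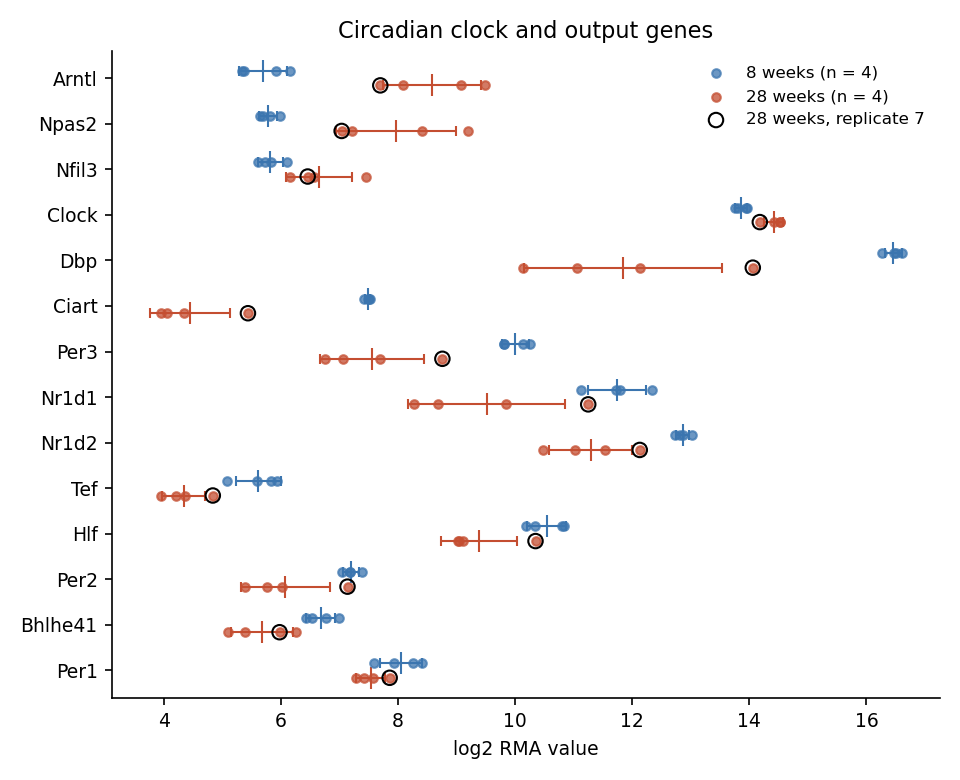
Log2 RMA values (x axis) of 14 circadian clock and output genes whose daily phase is known, with 1 point per mouse, ticks for group means, bars for SD (n = 4 per age), and a ring around 28-week replicate 7. The 4 genes at the top had higher means at 28 weeks and the 10 below had lower means, and 7 of the 14 passed the threshold (Arntl, Npas2, Dbp, Ciart, Per3, Nr1d2 and Tef).

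Lists of other tissues, sex and RNA quality were examined for the same arrays. Urothelium and pelvis markers were 1.71-fold higher at 28 weeks with none of 12 past the threshold over all probes or the list alone (camera adjusted p = 0.000967, and adjusted p = 0.275 with an estimated correlation). Psca was 4.63 ± 1.72 at 8 weeks and 7.71 ± 2.02 at 28 weeks (adjusted p = 0.178) and Upk3b had a log2 difference of 1.07. The urothelium list score was 0.655 in 8-week replicate 1 and -0.376, -0.0883 and -0.191 in the other 8-week mice. In 28-week replicates 6, 7, 8 and 9 it was 1.46, 0.952, 0.857 and -0.155, the last inside the range of the 8-week mice. Hepatocyte markers were called upwards (camera adjusted p = 0.0114, and adjusted p = 0.252 with an estimated correlation), with 2 of 16 past the threshold adjusted over the list alone. The serpin genes Serpina1b and Serpina1a had log2 differences of 2.07 and 1.71, and the call ended without 28-week replicate 7 (adjusted p = 0.0715). The unfolded protein list (camera adjusted p = 0.0415, and adjusted p = 0.338 with an estimated correlation) held the stress-response gene Atf4, which rose 1.89-fold (adjusted p = 0.042). Reference genes were 1.19-fold higher (camera adjusted p = 0.0384, and adjusted p = 0.27 with an estimated correlation), with log2 differences of 0.86 for Actb and 0.92 for B2m. Adjusted over the list alone 2 of 18 unfolded protein genes and 2 of 12 reference genes were higher. The unfolded protein call ended without 8-week replicate 1 (adjusted p = 0.142) or 3 (0.0547) and without 28-week replicate 6 (0.0986) or 9 (0.0655), and the reference gene call without 8-week replicate 3 (0.149) or 4 (0.0741) and without 28-week replicate 8 (0.0661).

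The remaining lists were not called. Camera adjusted p was 0.444 for genes of the developing and growing kidney, in which Igf2 rose and the imprinted gene Peg3 fell 2.54-fold (adjusted p = 0.0465), and 0.255 for senescence genes, in which Cdkn1a rose and Igfbp3 fell. It was 0.251 for antioxidant genes, with log2 differences of 0.77 for Gsta2 and -0.46 for Sod3, 0.49 for cholesterol synthesis (Mvd -0.52 and Fdps 0.56), and 0.879 for renin-angiotensin genes (Edn1 1.17 and Nr3c2 -0.37). Among lists of other tissues it was 0.434 for adipocyte markers, in which lipoprotein lipase (Lpl) fell 4.28-fold (adjusted p = 0.00782), 0.805 for adrenal markers (Hsd3b1 -0.26 and Mc2r 0.46), 0.11 for erythroid and platelet markers (Ppbp 0.42 and Pf4 0.35), and 0.933 for skeletal muscle markers, of which Pvalb fell. The Ppbp probe was dim, with means of 3.11 at 8 weeks and 3.53 at 28 weeks. Genes with higher expression in the male kidney (camera adjusted p = 0.57) included Slc22a30 and Nudt19, which fell, and Cyp4a12a, which rose. Those with higher expression in the female kidney (camera adjusted p = 0.698) included Cyp2a4, which rose 2.23-fold (adjusted p = 0.0192), and Cyp4a14, which fell. Nudt19 was 2.17-fold lower (adjusted p = 0.0423). For immediate early and dissection stress genes camera adjusted p was 0.0645 (Ier2 -0.52 and Klf6 1.2) and for ribosomal protein genes 0.0902 (Rps18 0.32 and Rpl15 0.30). The number of members higher and lower adjusted over the list alone was 1 and 1 of 25 for kidney growth, 1 and 2 of 17 for senescence, 1 and 0 of 21 for antioxidant, 1 and 1 of 13 for adipocyte, 0 and 1 of 12 for muscle, 4 and 3 of 13 for male-biased, and 2 and 2 of 10 for female-biased genes, and 0 in the other lists of this paragraph. The erythroid list was called without 8-week replicate 3 (adjusted p = 0.0467) or 28-week replicate 9 (0.0478). The stress list was called without 8-week replicate 2 (0.0465) or 28-week replicate 7 (0.0172) or 9 (0.0475), and the ribosomal list without 8-week replicate 1 (0.0126) or 2 (0.0256). In 4 of these lists (kidney growth, renin-angiotensin, adrenal and skeletal muscle) the median, the mean and the test did not share a sign. The Y-linked list had 3 measured genes, too few for the test.

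Camera called 33 of 54 lists at the preset correlation, 25 upwards and 8 downwards. With an estimated correlation it called none (lowest adjusted p = 0.252, with 10 lists at an unadjusted p under 0.05), and fry called 2, fatty acid oxidation and senescence (adjusted p = 0.0308 for both), with 29 at an unadjusted p under 0.05. The exact permutation test of the list score (70 arrangements, two-sided) reached its smallest possible p of 0.0286 in 16 of 55 lists, and the lowest Benjamini-Hochberg adjusted value was 0.0983. These were the MHC class II, lymphoid organising, TNF and NF-kappa-B, B cell, neutrophil, tubular injury, parietal, proximal tubule S1 and S2, thin limb, distal tubule, fatty acid oxidation, glycolysis, unfolded protein, senescence, hepatocyte and circadian lists. Without 28-week replicate 7 the number of lists with an exact p under 0.05 was 31, and without 8-week replicates 1, 2, 3 and 4 it was 5, 6, 4 and 3. As a median over all probes, the spread between mice of one age was not shown to differ between the ages. The median SD was 0.266 at 8 weeks and 0.228 at 28 weeks, and the median ratio of SDs, 28 weeks over 8 weeks, was 0.873 (exact two-sided p = 0.457 over 35 splits). Without 8-week replicate 1 the median log2 ratio was 0.18, where it was -0.20 with all arrays, and p was 0.257 by the same exact test. Single lists went either way, and their spread was not tested. The SD of the list score was 0.146 at 8 weeks and 1.25 at 28 weeks for macrophage markers, and 0.149 and 0.848 for tubular injury markers. For podocyte markers it was 0.212 at 8 weeks and 0.0875 at 28 weeks.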

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

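All tests of an explanation in this part were chosen after the results they concern had been seen. Of 352 groups of 4 values examined (named genes and list scores at each age), 24 held 1 mouse whose gap to the nearest of the others took most of the group's range, and chance gives about 1 in 20 groups, or 17.6. Of the 24 values 8 were in 28-week replicate 7, 7 in 8-week replicate 1, 4 in 8-week replicate 2, 3 in 28-week replicate 6, and 1 each in 8-week replicate 3 and 28-week replicate 9.

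In 28-week replicate 7, log2 values lay below those of the other 28-week mice for Vcam1 (8.01 against 10.2 to 10.4), Fcgr3 (9.35 against 10.2 to 10.4), Xcr1 (5.56 against 6.68 to 6.84), Ccl5 (3.8 against 5.07 to 5.29), Cldn1 (10.1 against 10.6 to 10.7), Pfkp (11.5 against 11.9 to 12), Edn1 (4.63 against 6.21 to 6.53) and the complement list score (0.0889 against 1.22 to 1.34). Over genes called from 3 arrays of each age, replicate 7 lay past the midpoint towards 28 weeks in 27.2%, 23.9%, 25.4% and 23.1% of genes, and the 8-week array left out of each fit in 19.2%, 3.35%, 6.99% and 3.26%. Its share was the higher one also in all 24 combinations of size limit, position and array tried, which argues against a mislabelled 8-week sample, with the narrowest margin against 8-week replicate 1. Differences shrunken alike by the array's quality would put replicate 7 at the same share of the difference in every list. Its score lay among those of the other 28-week mice for hepatocyte (0.608 against 0.441 to 0.721), thick ascending limb (0.508 against 0.163 to 0.616) and fatty acid oxidation genes (-0.189 against -0.329 to -0.148). For macrophage (0.147) and proliferation genes (-0.0524) it lay inside the 8-week range. These lists differ from that prediction. They were chosen among 55 after their scores were seen, so they do not decide against such shrinkage. On a scale from the 8-week mean (0) to the mean of the other 28-week arrays (1), the median position of the values of replicate 7 was 0.0656 for 147 immune and injury genes and 0.279 for 1090 others, a difference of -0.213 (permutation p = 1e-05, the smallest that 100000 resamples can give). Genes of a list vary together, which that p leaves out, and 0.0656 lies inside the quartiles of the other genes (0.0588 to 0.529), so that test alone decides nothing. Such shrinkage and other effects of the array's quality cannot be told apart from a milder disease or a smaller leukocyte infiltrate in that mouse, which stay open, as untested.

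In 8-week replicate 1, log2 values lay apart from the other 8-week mice for Ly6f (9 against 9.97 to 10), Ddx58 (8.6 against 9.14 to 9.22), H2-Ob (4.03 against 4.74 to 4.86), Ppbp (3.31 against 3.03 to 3.06), Umod (18.5 against 18.3), Slc34a1 (18.6 against 18.1) and the MHC class I list score (0.363 against -0.128 to -0.108). A lower background as the whole of the difference was argued against, because its deviations from the other 8-week arrays in the brightest 33.3% of probes had an SD of 0.532, 1.61 times the largest of the other 3 (0.331). Probes for chemosensory receptors, which a kidney is not known to express strongly, had a median of 4.03 on that array and 4.4 or more on all others but 28-week replicate 6 (3.95), so a lower background on part of the probes stays open. For the urothelial genes, more pelvis, ureter or hilum tissue in that sample was neither shown nor excluded: 7 of 12 members of the urothelium and pelvis list were highest in it, where 33.2% of all probes were (one-sided exact binomial p = 0.065; it was 0.014 against 1 in 4, the share first used). Members of one list vary together and other epithelia express some of them, so neither p is evidence for that tissue.

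The remaining values were in mice that stood apart in few genes. In 8-week replicate 2 the log2 value was 16.3 for S100g (others 15.6 to 15.7), 5.04 for Edn1 (others 4.64 to 4.65) and 12.4 for Lpl (others 12), and the lymphoid organising list score was -0.249 (others 0.0556 to 0.0974). In 8-week replicate 3 H2-Ab1 was 8.24 (others 8.81 to 8.87). In 28-week replicate 6 Nat8f5 was 5.56 (others 6.51 to 6.7), and the scores of the thin limb and senescence lists were 1.29 (others 0.372 to 0.516) and 0.287 (others 0.159 to 0.176). In 28-week replicate 9 Hsd3b1 was 4.96 (others 5.23 to 5.25).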

How the results depend on the processing

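Cyclic loess and the omission of 2 arrays together were chosen after seeing the data. No called result turned its direction in any setting, and all 215 changed probes that a setting tested kept their sign. Where arrays were left out or weighted, the sign of these probes was fixed in advance, because their groups did not overlap. It was also fixed with dim probes left out, 1 named probe per gene, trend and robust options, unequal variances or 1 surrogate variable. These settings leave the difference of means unchanged, so only the other normalizations could have turned a sign. Counts stayed within 1.5 times with array medians centred (177 probes), quantiles (247), cyclic loess (246), the dimmest 33.3% of probes left out (275) and 1 named probe per gene (239), and of the 215 changed probes 173 were called again with array medians centred, 203 after quantile normalization, 208 after cyclic loess and 185 when centred on ribosomal and reference genes. Centred on ribosomal and reference genes, 212 probes were lower. With the dimmest 50% of probes left out 399 changed (182 higher, 217 lower). For this and the following settings the cause of the different count was not tested. With trend and robust options 399 changed (183 higher, 216 lower), with array weights 873 (525 higher, 348 lower, 500 at least 2-fold), and with 1 surrogate variable 677 (384 higher, 293 lower, 387 at least 2-fold). Without 8-week replicate 1 and 28-week replicate 7 together it was 1384 (930 higher, 454 lower, 866 at least 2-fold). An unmoderated test with unequal variances called 0 probes, 0 higher, 0 lower and 0 at least 2-fold, with 2568 at an unadjusted p under 0.05, where limma gave 215 and 3329. Under an adjusted p of 0.01 limma called 18, and treat called 16. With 1 array left out, 25 (without 28-week replicate 9) to 1237 (without 28-week replicate 7) probes changed, 5 to 805 were higher, 18 to 432 lower and 25 to 834 at least 2-fold. Lists called numbered 33, against 0 with an estimated correlation (10 at an unadjusted p under 0.05), 2 with fry and 33 on ranks, and 32 to 35 with 1 array left out. Lists with a score p under 0.05 numbered 16, 13 by the median of members, and 3 (without 8-week replicate 4) to 31 (without 28-week replicate 7) with 1 array left out. Unequal groups allow arrangements that equal groups do not, so these last counts are not directly comparable with 16. The log2 ratio of SDs, -0.196, ranged from -0.341 to -0.108 in the fits without 1 array other than 8-week replicate 1, where it was 0.177. Of the values for named genes with 1 array left out, 695 kept their side of the threshold, 42 passed newly and 207 passed no longer, and in other settings 1170, 147 and 62. For lists these numbers were 404, 15 and 13, and in other settings 396, 8 and 77. Signs of genes or lists without a call turned in 13 values for genes and 17 for lists. No paired analysis was possible because the groups share no replicate numbers. Dim probes lie near the background of the arrays, where RMA compresses differences.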

Other observations

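The gene families and the tests of this part were chosen after their values were seen. Single genes past the threshold that the report does not name are given here as values, and no family among them was tested as a group. The carboxylesterase genes Ces1d, Ces1e and Ces2b were 3.62-fold, 2.5-fold and 2.91-fold lower, and the organic anion transporter family genes Slc22a28, Slc22a22 and Slc22a29 were 4.23-fold, 2.97-fold and 2.56-fold lower. Nat8, of the same family as the Nat8f genes, was 3.94-fold lower (adjusted p = 0.0281). Paralogs in these families are close in sequence, so shared probe signal leaves their separate folds uncertain. Pcx, which encodes the gluconeogenic enzyme pyruvate carboxylase, was 12.62 ± 0.20 at 8 weeks and 10.48 ± 0.45 at 28 weeks (adjusted p = 0.00506, n = 4 arrays at each age by limma).

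The tubulin genes Tuba1a, Tuba1b, Tuba1c and Tubb4b were 3.26-fold, 2.48-fold, 2.12-fold and 2.04-fold higher, also with the reservation on paralogs. Other tubulin genes did not pass, among them Tubb5 (log2 difference 1.94, adjusted p = 0.0501), Tubb6 (1.27, adjusted p = 0.166) and Tuba4a (0.25, adjusted p = 0.668). The lactate and pyruvate transporter gene Slc16a1 was 3.82-fold higher, and the glutamine transporter genes Slc38a2 and Slc38a3 were 2.94-fold and 2.53-fold higher. Slc38a2 was 12.66 ± 0.11 at 8 weeks and 14.22 ± 0.37 at 28 weeks (adjusted p = 0.00997). The aldo-keto reductase gene Akr1c21 was 3.07-fold higher (adjusted p = 0.0373).

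Clock genes differed between the ages in both directions: of 19 measured members of the clock list 14 were given a daily phase from textbook knowledge, and in 14 of these the sign was the one that a shared shift of phase predicts, 4 up and 10 down. The phases were given after the values were seen, so this count does not test a shift of phase. Fewer kidney cells of all segments alike were argued against only weakly. Per mouse, the median deviation of the 19 clock list members minus that of 122 kidney epithelial markers differed between the ages by -0.832 (exact two-sided permutation p = 0.0286, the smallest possible). In 28-week replicate 7 that value was -0.138, beside -0.131 in 8-week replicate 1, so the difference rests on 28-week replicates 6, 8 and 9 (-1.13, -1.06 and -0.989). Fewer distal tubule cells stay open for the genes that fell (difference of medians from that list -0.61, permutation p = 0.31), because a median over members moving both ways cannot decide it. They leave unexplained the 4 members that rose adjusted over the list alone, among them Arntl (log2 difference 2.89) and Npas2 (2.18). The test per mouse was the last of 4 forms tried, after a comparison with the spread of single genes and permutations of genes that gave -1.24 for the falling-phase genes (p = 3e-05) and -0.83 for the whole list (p = 9e-05), the last of which left all kidney cells open because of the distal tubule. Another time of day at collection cannot be told apart from the age of the mice, since the labels give no collection time and each group is one age, and an effect of age or disease on the kidney clock stays open, as untested.

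Other groupings of the same 8 arrays were counted over all 35 splits into 4 and 4. For changed probes 1 split, the real one, gave as many (215, highest other 6). For probes higher (99), lower (116) and at least 2-fold (164) it was 1 split each, the highest other being 6 in each case (in the larger direction for higher and lower). This argues against chance for these counts but does not exclude it, because 1 of 35 is the smallest share that the splits can give. The counts come from the same fit and are not separate tests. For lists called by camera 1 split gave as many (33), and the highest other was 32, in the split of 8-week replicate 1 and 28-week replicates 6, 8 and 9 against the rest. With a margin of 1 list, and with lists called in simulated data from array effects alone, that count is not taken to exclude chance.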
